A study of Macaca mulatta with 8 samples.

How the data were processed

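Mural granulosa cells, the somatic cells that line the wall of the ovarian follicle, were collected from rhesus macaques under follicle-stimulating hormone (FSH) alone or after a further ovulatory stimulus with human chorionic gonadotropin (hCG), per the labels and the series design. The samples are 4 RNA preparations per group, each on its own Affymetrix rhesus macaque array, so 8 arrays in all. Per the labels' protocols, total RNA was purified with a small-sample kit, amplified linearly over repeated cycles of reverse transcription and transcription in vitro, and labelled with biotin. The sample source labels speak of granulosa cells from cumulus-oocyte complexes, whereas the series design speaks of mural granulosa cells, and the design's wording was followed. The time between hCG and collection, the animal or follicle behind each replicate and any scan batch are not given in the sources used here, so the replicates may share animals and batch cannot be examined. P-values therefore measure the spread between these samples only, and that spread may be partly technical. The cumulus cell arrays that the series design mentions were not analysed here.

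The deposited table holds intensity values, made by the authors with Affymetrix Expression Console and robust multi-array average (RMA), per the submitters' processing notes; their versions are not given in the sources used here. RMA values are usually stored as log2, but the deposited values are on a linear scale, with array medians of 43.5 to 46.5, so log2 was taken first and nothing else was changed. The table has 52865 rows. Of these, 99 array controls were left out, which left 52766 probe sets. GEO's platform annotation gave 1 gene symbol to 24956 probe sets, several to 361 and none to 27449. Of the 24956, 24616 had a gene ID in the reference gene table, through which symbols were updated; the others kept the platform's symbol. Probe sets with several symbols or none were tested but not named. The table carries no detection calls, so no gene is called present or absent, and the number of arrays limits the precision.

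The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, as after hCG minus before hCG, with Benjamini-Hochberg adjustment and a threshold of 0.05 on the adjusted p. This was done over all probe sets and over 14132 genes, each represented by the probe set with the highest mean log2 value over all 8 arrays; 6375 of these genes have several probe sets. Values are log2 intensities, given as mean ± SD with n = 4 per group, and changes are log2 differences with their standard error (SE). Measures of array quality were compared by exact two-sided permutation tests, whose smallest possible p for 4 against 4 arrays is 0.0286.

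A total of 35 gene lists were fixed before the data were examined: ovulatory response, FSH-stimulated granulosa, progesterone synthesis, cholesterol uptake and transport, cholesterol synthesis, cell division, DNA replication, cell cycle inhibitors, extracellular proteases and inhibitors, hyaluronan matrix, collagens and basal lamina, prostaglandin synthesis and receptors, angiogenesis, glycolysis, oxidative phosphorylation, unfolded protein response, immediate early genes, cytokines and chemokines, TGF-beta and BMP signalling, WNT signalling, EGF receptor signalling, cAMP signalling, gap and adherens junctions, apoptosis regulators, glucocorticoid metabolism and response, interferon response, ribosomal proteins, cumulus-enriched genes, and markers of oocytes, theca, endothelium, leukocytes, erythrocytes, stroma and surface epithelium. Of their 751 entries, 541 (72%) could be matched to a measured gene. Each list was tested with limma's camera at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 35 lists. Camera compares a list with all other genes. It was repeated with the correlation estimated from the data, and with fry, which tests whether a list's genes move one way on balance and does not compare them with other genes. Counts of members past the threshold are over all genes unless "adjusted over the list alone" is written.

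The genes named in the text follow a rule fixed in advance. It takes 27 index genes of ovulation and steroid synthesis, of which 17 had a probe set with a single symbol. It adds the 12 largest increases and the 12 largest decreases among genes past the threshold with no overlap between the groups, leaving out uninformative symbols. It also adds up to 3 members per list and direction past the threshold and, for lists of other cell types, the 3 members with the highest mean signal. It gave 147 genes. A few further list members, named for contrast, were chosen after their values were seen: GAPDH, ENO1, KRT8, IL1B, LHX9, RUNX2, TNFAIP3 and ADAMTS9.

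The procedure was tested on simulated data built from the spread of the 8 arrays, with 200 of 14132 genes changed, in 20 runs. Planted changes of 0.5, 1 and 2 on the log2 scale were recovered in 17.7%, 71.3% and 94.5% of cases. In the real data 3359 genes passed, and the Benjamini-Hochberg adjustment is less strict where more genes change. These recovery rates therefore hold for the simulated setting and do not carry over to the real data. On average 4.89% of the called genes were false, the planted list was found in 20 of 20 runs, and 0.147% of unplanted lists were called. The simulated genes varied independently of each other. In the real data the estimated inter-gene correlation was, for example, 0.22 for cell division and 0.252 for glycolysis. The share of unplanted lists called therefore gives no error rate for lists whose genes vary together. The alternatives tried were a replicate block, a filter on low signals, repeated quantile normalization, median centring, an offset of 32 added to each intensity, leaving out each array in turn, an intensity trend with robust variances, array quality weights, an adjusted p threshold of 0.01, a minimum change of 1 on the log2 scale, and averaging all probe sets of a gene.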

Results

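The data are 8 arrays of rhesus macaque granulosa cells, 4 from follicles under FSH alone (before hCG) and 4 from follicles after the ovulatory stimulus (after hCG). The median log2 intensity per array lay between 5.44 and 5.54. No pair of arrays was identical. Pearson correlations across probe sets were 0.984 to 0.988 within the group before hCG, 0.975 to 0.984 within the group after hCG and 0.935 to 0.956 between the groups. The first principal component carried 61.2% of the variance and separated the groups. The difference between 3' and 5' probe sets of ACTB, often used as a measure of RNA integrity, was 4.75 ± 0.0523 before and 4.77 ± 0.312 after hCG (SD, n = 4, exact permutation p = 0.914). After hCG it was 5.18 in array 3 and 4.47 in array 1, the highest and the lowest of the 8 arrays. The RNA had been amplified, and how far that shaped this difference was not tested. The same difference for GAPDH was 2.76 ± 0.0741 before and 2.66 ± 0.0996 after hCG (exact permutation p = 0.171).

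The comparison asks how the transcripts of these cells differ after the ovulatory stimulus. After hCG, AREG, an EGF-like growth factor, rose from 4.15 ± 0.24 to 10.91 ± 0.90 (SD, n = 4, log2 change 6.77, SE 0.38, adjusted p = 4.28e-06). PTX3, a protein of the hyaluronan matrix, rose by 6.74 (SE 0.34). STAR, which carries cholesterol into mitochondria for steroid synthesis, rose 12.1-fold, from 8.92 ± 0.62 to 12.52 ± 0.66. CYP19A1, the aromatase that makes oestrogens, was 4.22-fold lower, at 9.60 ± 0.62 before and 7.52 ± 0.21 after hCG. MKI67, a marker of dividing cells, was 7.97-fold lower, at 9.80 ± 0.32 before and 6.80 ± 0.30 after hCG (adjusted p = 9.46e-06).

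Of 14132 genes, 3359 (23.8%) passed the threshold, 1595 higher and 1764 lower after hCG. Among them, 866 rose and 612 fell at least 2-fold, and 148 rose and 24 fell at least 8-fold. The groups did not overlap for 3838 genes (27.2%, against 2.86% by chance), and 3042 of these passed the threshold. Of the 52766 probe sets, 7434 (14.1%) passed, 3820 higher and 3614 lower, and 2564 of them have no gene symbol or several. Without array 3 after hCG, 3348 genes passed (2965 of them shared), and without array 1 after hCG 2897 (2734 shared). The share of higher genes, 47.5%, was 40.8% after repeated quantile normalization and 52.4% after median centring.

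The largest increase was that of MOCOS, which activates molybdenum enzymes, from 3.60 ± 0.28 to 10.69 ± 0.24 (log2 change 7.09, SE 0.17, adjusted p = 7.09e-08). AREG, PTX3, TM4SF1, TFPI2 (an inhibitor of serine proteases), HSD11B1, GPRC5B, APCDD1 (an inhibitor of WNT signals), TMEM200C, AADAC, KCNG3 (a potassium channel subunit) and RORA (a nuclear receptor) followed, with increases of 5.44 to 6.77. MOCOS, AREG, PTX3, TM4SF1, TFPI2, TMEM200C, AADAC and KCNG3 started below the median signal of the arrays, where the fold depends on the background correction. With 32 added to each intensity, the log2 increase was 5.25 for MOCOS, 5.30 for AREG and 4.47 for PTX3. Without array 4 after hCG, which read 7.70 for TMEM200C, its increase was 6.40 in place of 5.61, and without array 1 after hCG that of AADAC was 6.24 in place of 5.53. TFPI2 has 5 probe sets, of which 3 rose and 1 fell, and their average rose by 2.54. The averages of all probe sets also rose by less for TM4SF1 (4.004), GPRC5B (3.92), AADAC (3.10) and KCNG3 (2.81).

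The largest decrease was that of SLC30A4, a zinc transporter, which went from 12.44 ± 0.23 to 7.26 ± 0.22 (36.1-fold lower, SE 0.16 on the log2 scale, adjusted p = 2.58e-07); the average of its 2 probe sets fell by 2.71. MAP6D1, SUOX (the molybdenum enzyme sulfite oxidase), SLC35G1, SPATA17, EFNB1 (a membrane-bound ephrin), ELOVL6 (a fatty acid elongase), HSDL1, CYP11B1, RAB17, IFT46 and HSPB6 fell by 3.50 to 4.94. The average of all probe sets of SUOX fell by 2.56, that of HSPB6 fell by 2.19 and that of IFT46 fell by 1.79, with 1 of the 2 probe sets of IFT46 at -0.03. EFNB1 went from 11.27 ± 0.15 to 7.30 ± 0.25. Without array 4 after hCG, MAP6D1 fell by 4.15 in place of 4.94. CYP11B1, an enzyme of cortisol synthesis in the adrenal gland with a near-identical paralog that the probes may also bind, varied widely before hCG (8.31 ± 2.37). Its decrease of 3.69 was 2.58 without array 2 before hCG and 4.44 without array 3 before hCG, and it did not pass with 32 added to each intensity (adjusted p = 0.0793); the average of its probe sets fell by 2.17.

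**Figure D1:**
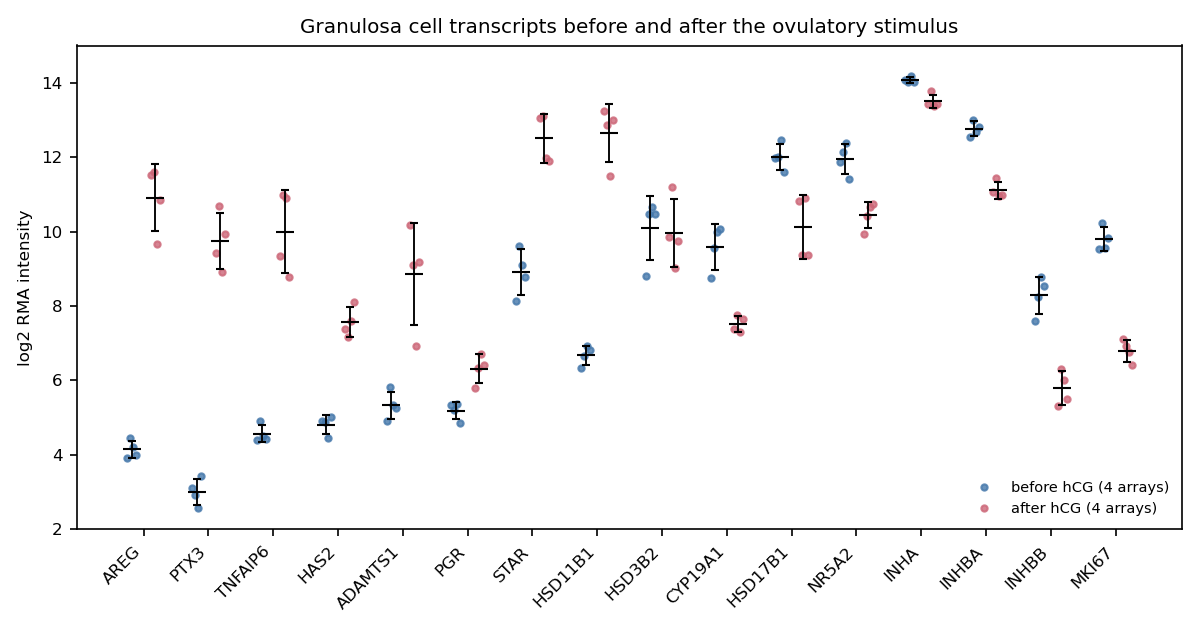
Log2 RMA intensity (y axis) of 16 genes in each of the 4 arrays before hCG (blue) and the 4 arrays after hCG (red), with the mean and SD in black. AREG lay at 4.15 before and 10.91 after hCG on average, while HSD3B2 overlapped between the groups.

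The ovulatory response list, genes known to be induced in follicles around ovulation, rose as a group (median log2 change 1.39, adjusted p = 6.56e-09, and adjusted p = 0.0312 with an estimated correlation). Of its 19 measured genes, 14 rose, 1 fell and 4 did not pass. Adjusted over the list alone, 15 rose and 2 fell. Of the 19, 11 are also in other lists. For some members other probe sets rose more than the brightest one. RUNX2 did not pass at -0.20, but 1 of its 5 probe sets rose, with changes up to 5.88. TNFAIP3 did not pass, with 2 of 5 probe sets higher. ADAMTS9 rose by 0.88, with 4 of 5 probe sets higher and changes up to 6.84. Besides AREG and PTX3, TNFAIP6, which links proteins to hyaluronan, rose by 5.43 (SE 0.46), HAS2, a hyaluronan synthase, by 2.75 (SE 0.21), and ADAMTS1, a matrix protease, by 3.52 (SE 0.57). The increase of ADAMTS1 was 4.16 without array 3 after hCG. RGS2, a regulator of G protein signals, rose by 3.70. PGR, the progesterone receptor, rose 2.18-fold from a low signal of 5.19 ± 0.23. NRIP1, a nuclear receptor corepressor, was the member that fell, by 1.67.

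Extracellular proteases and inhibitors also rose as a group (median 0.87, adjusted p = 1.4e-05, and adjusted p = 0.0327 with an estimated correlation). Of 22 measured genes, 11 rose, none fell and 11 did not pass, with the same counts of 11 and 0 adjusted over the list alone. Of the 22, 4 are also in other lists, all of them in the ovulatory response list, so these lists are not independent. MMP10 rose by 3.88 (SE 0.76), with 4.48 without array 2 after hCG and 3.14 without array 4 after hCG. TIMP1, an inhibitor of metalloproteinases, rose by 3.33 (SE 0.15), and the average of its 3 probe sets rose by 1.06. In the hyaluronan matrix list, 5 of 15 genes rose, 3 fell and 7 did not pass (the same counts of 5 and 3 adjusted over the list alone), and the list as a whole did not pass (median 0.11, adjusted p = 0.131). HYAL2, a hyaluronidase, fell by 0.87. Among collagens and basal lamina, 5 of 17 rose, 3 fell and 9 did not pass, and 6 and 3 adjusted over the list alone (adjusted p of the list = 0.274). FN1, fibronectin, rose by 3.21 (SE 0.50) and LAMB1, a laminin chain, by 1.82, while LAMA1, another laminin chain, fell by 1.37.

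Genes typical of FSH-stimulated granulosa cells were lower (median -0.63, adjusted p = 0.001, but adjusted p = 0.233 with an estimated correlation). Of 20 measured genes, 11 fell, 1 rose and 8 did not pass, with the same counts of 11 and 1 adjusted over the list alone. The subunits of inhibin and activin fell: INHBB by 2.50 (SE 0.29), INHBA by 1.65 (SE 0.15) and INHA by 0.57 (SE 0.12). IHH, a hedgehog ligand, fell by 2.96, HSD17B1, which makes oestradiol from oestrone, by 1.90, and NR5A2, a nuclear receptor that controls steroid enzymes, by 1.51. ESR2, an oestrogen receptor, was at 6.76 ± 0.12 before and 6.56 ± 0.13 after hCG (adjusted p = 0.253). IGFBP5, which binds insulin-like growth factors, rose by 1.35.

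Genes on the list of progesterone synthesis changed in both directions, with 5 of 11 higher, 4 lower and 2 not past the threshold, the same counts of 5 and 4 adjusted over the list alone (median 0.05, adjusted p of the list = 0.274). CYP11A1, a listed enzyme of this pathway, could not be matched to a measured gene, so the counts leave it out. Beside STAR, CYB5A, a cytochrome that assists steroid enzymes, rose by 1.91 (SE 0.19), while the electron donors POR and FDXR fell by 1.94 (SE 0.18) and 1.41 (SE 0.17); the average of the 4 probe sets of POR fell by 1.26. HSD3B2, which makes progesterone and whose probes may also bind its paralog, was at 10.10 ± 0.86 before and 9.96 ± 0.91 after hCG (adjusted p = 0.865). HSD11B1, which regenerates active glucocorticoid from its inactive form, rose by 5.97 (SE 0.34, adjusted p = 4.54e-06), a 62.8-fold increase. It is counted among the 5 higher genes of the progesterone list although it acts on glucocorticoids, and it is counted again in the glucocorticoid list. The list of glucocorticoid metabolism and response was higher (median 0.49, adjusted p = 0.000281, but adjusted p = 0.156 with an estimated correlation). In it 5 of 13 genes rose and 8 did not pass, and adjusted over the list alone 6 rose and 1 fell. Its risers include FKBP5 (3.26, SE 0.32) and ZBTB16 (2.92, SE 0.18), both known to be induced by glucocorticoids and progestins.

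Of 10 genes of cholesterol uptake and transport, 2 rose, 3 fell and 5 did not pass, and 2 and 4 adjusted over the list alone (median -0.25, adjusted p of the list = 0.788). NPC1, which exports cholesterol from lysosomes, rose by 1.71, and STARD4, a cholesterol carrier of the cytosol, fell by 1.61. Of 15 genes of cholesterol synthesis, 3 rose, 1 fell and 11 did not pass, the same 3 and 1 adjusted over the list alone. HSD17B7 rose by 2.92 (SE 0.20) and DHCR7 by 2.13, and TM7SF2 was 4.01-fold lower; the average of its 3 probe sets fell by 1.28. This list did not pass (median 0.42, adjusted p = 0.0615), but it did without array 2 before hCG (adjusted p = 0.0239) and without array 1 after hCG (adjusted p = 0.0247).

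Transcripts of cell division were lower (median -1.95, adjusted p = 3.46e-12, but adjusted p = 0.118 with an estimated correlation). Of 18 measured genes, 17 fell and 1 rose, and the counts were the same adjusted over the list alone. Beside MKI67, CDK1, the kinase that starts mitosis, fell by 2.85 (SE 0.40) and NCAPG, a condensin subunit, by 2.61 (SE 0.21). The gene that rose was TPX2, a spindle protein measured by 1 probe set, by 1.09 (SE 0.22). DNA replication genes were also lower (median -1.36, adjusted p = 2.71e-07, but adjusted p = 0.233 with an estimated correlation), with 14 of 18 lower, none higher and 4 not past, the same 14 adjusted over the list alone. MCM3, a subunit of the replicative helicase, fell by 1.94 (SE 0.30). Of 12 cell cycle inhibitors, 3 rose, 1 fell and 8 did not pass, the same 3 and 1 adjusted over the list alone. CDKN1A, an inhibitor of cyclin-dependent kinases, rose by 3.68 (SE 0.13), and the stress-response genes GADD45A and GADD45B rose by 4.24 and 4.02; the average of the 3 probe sets of GADD45A rose by 1.52. This list did not pass (median 0.06, adjusted p = 0.067), but it did without array 3 after hCG (adjusted p = 0.0242).

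Glycolysis genes were higher as a list (median 0.43, adjusted p = 0.00233, but adjusted p = 0.376 with an estimated correlation). Of 18 genes, 5 rose and 13 did not pass, the same 5 adjusted over the list alone. The glucose transporter SLC2A3 rose by 2.61 (1.17 for the average of its 4 probe sets), and the isoenzymes ALDOC and ENO2 by 2.13 and 2.01, while the abundant GAPDH and ENO1 differed by -0.05 and 0.02 (adjusted p = 0.898 and 0.914). Oxidative phosphorylation genes were slightly lower (median -0.34, adjusted p = 0.0456, but adjusted p = 0.542 with an estimated correlation). Of 20 genes, 7 fell and 13 did not pass, the same 7 adjusted over the list alone; UQCRFS1 fell by 0.85 and NDUFS1 by 0.83; the average of the 2 probe sets of NDUFS1 fell by 0.49. The oxidative phosphorylation call was lost when probe sets were averaged (adjusted p = 0.0594), with a filter of low signals (adjusted p = 0.0589), and without array 3 or 4 before hCG (adjusted p = 0.0931 and 0.0884) or array 2 or 4 after hCG (adjusted p = 0.0871 and 0.061).

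Among angiogenesis genes, 5 of 17 rose, 1 fell and 11 did not pass, and 5 and 2 adjusted over the list alone (median 0.10, adjusted p of the list = 0.2). NRP1, a co-receptor of vascular growth factors, rose by 3.66 (SE 0.45), with 1.70 for the average of its 3 probe sets. ANGPT1 rose by 2.70 (SE 0.59) and PROK1 fell by 1.05 (SE 0.12). Of 13 genes of gap and adherens junctions, 4 rose and 9 did not pass, and adjusted over the list alone 5 rose and 2 fell. The tight junction proteins F11R, CLDN1 and CLDN3 rose by 4.73 (SE 0.40), 4.13 (SE 0.28) and 2.66 (SE 0.16). The junction list did not pass (adjusted p = 0.067), but it did without array 1 after hCG (adjusted p = 0.0478).

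Of 27 genes of TGF-beta and BMP signalling, 2 rose, 6 fell and 19 did not pass, the same 2 and 6 adjusted over the list alone (median -0.20, adjusted p of the list = 0.379). BMP6, a growth factor, and FSTL3, a binder of activins, rose by 2.38 and 2.13, and ID3, a target of BMP signals, fell by 2.44; the average of the 3 probe sets of ID3 fell by 0.89. Of 12 genes of EGF receptor signalling, 2 rose, 1 fell and 9 did not pass, and 3 and 1 adjusted over the list alone (adjusted p of the list = 0.175).

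The 14 cumulus-enriched genes, 12 of which are also in other lists, were higher as a list (median 0.33, adjusted p = 0.0364, but adjusted p = 0.233 with an estimated correlation). Of them, 3 rose, 1 fell and 10 did not pass, the same 3 and 1 adjusted over the list alone. The 3 are PTX3, TNFAIP6 and HAS2. The cumulus-enriched call was lost when probe sets were averaged (adjusted p = 0.0594), with 32 added to each intensity (adjusted p = 0.0676), with a filter of low signals (adjusted p = 0.0724), without array 1 before hCG (adjusted p = 0.0573) and without array 4 after hCG (adjusted p = 0.058).

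**Figure D2:**
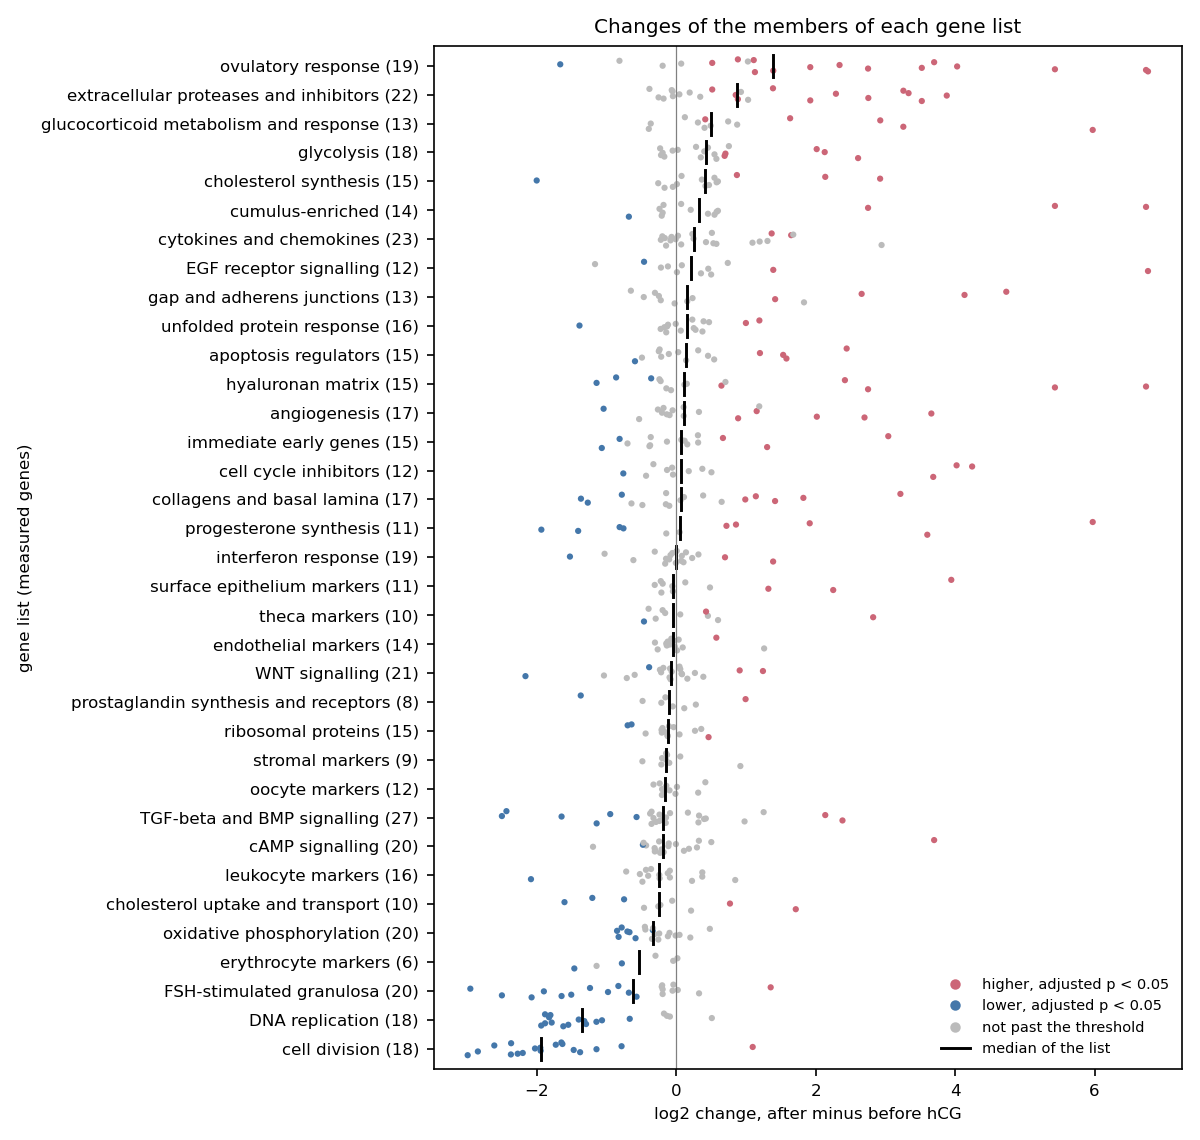
Log2 change after minus before hCG (x axis) of the measured members of each of the 35 gene lists, ordered by median (black line), with members past the threshold in red (higher) or blue (lower) and the others in grey. Medians ran from -1.95 for cell division to 1.39 for the ovulatory response.

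None of the 7 lists of markers of other cell types passed with camera. With fry, surface epithelium markers passed as higher (adjusted p = 0.0195) and erythrocyte markers as lower (adjusted p = 0.0404). Their medians lay between -0.54 and -0.05. Of 12 oocyte markers none passed (adjusted p of the list = 0.769); ZP4, an egg coat protein, was at 8.64 ± 0.23 before and 8.95 ± 0.28 after hCG. Of 16 leukocyte markers, 1 fell and 15 did not pass (adjusted p of the list = 0.665): CSF1R, the receptor of macrophage growth factor, fell by 2.09, while TYROBP differed by -0.09 (adjusted p = 0.91). Of 14 endothelial markers, 1 rose and 13 did not pass (adjusted p of the list = 0.87), with PECAM1 at 6.70 ± 0.34 before and 6.71 ± 0.69 after hCG. VWF differed by 1.26 (adjusted p = 0.138, or 0.0217 without array 3 after hCG). Of 9 stromal markers none passed (adjusted p of the list = 0.851), with DCN differing by 0.92 (adjusted p = 0.0844, or 0.00168 without array 2 after hCG). Of 6 erythrocyte markers, 2 fell and 4 did not pass (median -0.54, adjusted p of the list = 0.221). HBA fell by 1.47 and ALAS2 fell by 0.78. The HBA call was lost without array 2, 3 or 4 before hCG (adjusted p = 0.0956, 0.0741 and 0.0881) without array 1 or 3 after hCG (adjusted p = 0.0719 and 0.0758), and with 32 added to each intensity (adjusted p = 0.0604). The ALAS2 call was lost without array 3 before hCG (adjusted p = 0.0539) and array 1 or 2 after hCG (adjusted p = 0.0649 and 0.0535), and when probe sets were averaged (adjusted p = 0.085). Of 10 theca markers, 2 rose, 1 fell and 7 did not pass (adjusted p of the list = 0.729); HHIP, an inhibitor and target of hedgehog signals, rose by 2.82 (SE 0.45). Of 11 surface epithelium markers, 3 rose and 8 did not pass (adjusted p of the list = 0.198): WT1 rose by 3.94 and KRT18 by 2.25, both also known from granulosa cells, while KRT8 differed by -0.05 (adjusted p = 0.848) and LHX9 by -0.20 (adjusted p = 0.46). Of these lists, 5 of the 9 stromal and 3 of the 14 endothelial markers are also in other lists, and 15 of the 16 leukocyte, 10 of the 14 endothelial, 8 of the 10 theca, 7 of the 11 surface epithelium, 5 of the 12 oocyte, 4 of the 9 stromal and 3 of the 6 erythrocyte markers lay above the median signal before hCG. The medians of the theca, endothelial and surface epithelium lists were below 0 and their means above it (0.28, 0.05 and 0.64). Adjusted over the list alone, the counts higher and lower were 0 and 0 for oocyte, 0 and 1 for leukocyte, 1 and 0 for endothelial, 0 and 0 for stromal, 0 and 3 for erythrocyte, 2 and 2 for theca and 3 and 0 for surface epithelium markers.

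In all, 9 of 35 lists passed with the preset correlation, 5 higher and 4 lower, and 2 of them, the ovulatory response and the extracellular proteases, with the estimated correlation. Of the genes the naming rule gave, 131 passed, and 24 of these lost the call in at least 1 fit without 1 array. Averaging all probe sets of a gene gave smaller changes for some: MKI67 then fell by 1.64 and CDK1 by 1.41, and F11R rose by 2.25 and WT1 by 2.04. CLDN1 then rose by 2.50, RGS2 by 2.41, FN1 by 2.05 and KRT18 by 1.01, and IHH fell by 1.91. With 32 added to each intensity, MMP10 rose by 2.44, LAMB1 by 1.16 and PGR by 0.71.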

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

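Of the tests in this part, those on the mix of cells behind the fall in cell division, on the signal floor by the signal before hCG, and on weak against bright signals were set only after the results were seen, while those on scaling and RNA integrity were planned and the limits of what they show were seen afterwards. Among the groups of 4 arrays examined, 300 in all, 12 held an array far from the other 3, and chance alone would give about 15. The measure is the gap between that array and its nearest neighbour as a share of the group's range.

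Before hCG, ANGPT1 was at 4.42 in array 2 and between 5.57 and 5.65 in the others (gap 0.931 of the range). ANPEP was at 10.36 in array 1 before hCG and between 10.14 and 10.16 in the others (0.936). FOSL2 was at 11.05 in the same array and at most 10.07 in the others (0.94). HSD3B2 was at 8.81 in that array and between 10.46 and 10.67 in the others (0.887).

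After hCG, FSTL3 was at 9.89 in array 1 and between 10.31 and 10.37 in the others (0.883). IL1R2 was at 10.96 in array 1 and between 9.87 and 10.02 in the others (0.867). INHA was at 13.77 in array 2 and between 13.37 and 13.43 in the others (0.845). UPK3B was at 8.20 in array 2 and between 7.81 and 7.84 in the others (0.929). GADD45B was at 10.31 in array 3 and between 11.45 and 11.57 in the others (0.908). PDE8A was at 7.99 in array 4 and between 8.45 and 8.52 in the others (0.863). RGS2 was at 13.87 in array 4 and between 12.70 and 12.81 in the others (0.901). TMEM200C was at 7.70 in array 4 and between 10.59 and 11.12 in the others (0.843).

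Transcripts of cell division fell, with a median of -1.95 over 18 genes. As the whole source, a smaller share of granulosa cells among the cells collected would lower the transcripts of these cells alike and raise the markers of other cell types, but the median of the FSH-stimulated granulosa list was -0.63 (quartiles -1.54 and -0.16), 1.32 above that of cell division (permutation p = 0.0019 on ranks of the members, 1.18 to 1.44 with 1 array left out), and 0 of 7 lists of other cell types had a median of 0.3 or more. A partial effect of the mix of cells stays open, since the stimulus also acts on the granulosa list and the 78 members of those 7 lists, many of them weak, gave a permutation p = 0.105 on ranks for a difference between the lists, but 0.0192 on values and 0.0452 on ranks of the 52 members above the median signal. All these permutations treat genes as independent, though the estimated inter-gene correlation was 0.22 for cell division and 0.101 for the granulosa list. Their p may therefore be too low. For a loss of signal common to transcripts of this abundance, 10000 random lists of the same size and mean signal were drawn. Of these, 0% had a median as low, and the lowest reached -0.65. RMA had already brought the arrays close to a common distribution by quantile normalization, which removes most of such a loss. The medians of the random lists were therefore bound to lie near 0 (their own median was -0.0691), and this test cannot decide that explanation. A lower rate of division after the ovulatory stimulus is a candidate explanation that stays open, since no cells were counted here.

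Large increases outnumbered large decreases, with 148 against 24 genes at 8-fold, a ratio of 6.17 (95% interval 3.99 to 9.93). Genes that start near the signal floor can rise but not fall 8-fold; among genes chosen by their signal before hCG, up to 10.7 on the log2 scale, the ratio was 3.62 from a signal of 6.23 (58 against 16, interval 2.06 to 6.76) but 1.15 from 8 (15 against 13, interval 0.512 to 2.63), so the floor cannot be told apart. Under repeated quantile normalization the ratio was 5.42 and under median centring 7.45, both above the planned limit of 2. These corrections thus left the pattern in place. Both moved the median change of all genes by less than 0.1, too little to test a larger difference in scaling, which therefore cannot be told apart. No biological source of the ratio was tested.

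With all 8 arrays, those after hCG varied more between replicates, with a median ratio of variances, after over before, of 1.16 over all probe sets, but with 1 array left out it ranged from 0.923 to 1.45, so its direction rests on single arrays. Noise of weak signals would raise the ratio most below the median signal, but it was 1.07 there and 1.25 above it, a difference of 0.186 that stayed over 0 in all 8 fits without 1 array (0.0779 to 0.268). The criterion planned first was a ratio over 1.1 above the median signal in all 8 of these fits, and it was not met. That ratio was 1, 1.05 and 1.09 without array 1, 3 or 4 after hCG. Without array 3 after hCG, the one farthest in the ACTB difference, the ratio over all probe sets was 1.01, but it was 0.923 without array 1 and 1.01 without array 4 after hCG, so RNA integrity of that array cannot be told apart from other sources. Among probe sets with an unadjusted p above 0.5 the ratio was 1.16 (0.919 to 1.45 with 1 array left out), so a spread confined to responding genes cannot be told apart either. Differences between animals in the time course after hCG were not tested.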

How the results depend on the processing

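All settings here were planned before the data were examined. Under those other than a stricter threshold or another list test, the genes past the threshold numbered 2699 to 3539 (2699 to 3348 with 1 array left out), the probe sets 5682 to 7712 (5682 to 7101) and the lists 7 to 11 (7 to 11). Lists were not tested under the intensity trend or the array weights, and averaging probe sets gives no count of probe sets. At an adjusted p under 0.01, 4034 probe sets and 1940 genes passed, and with a change of at least 1 on the log2 scale 3511 and 1478 did; both settings are stricter by construction. With an estimated correlation 2 lists passed (the cause was not tested), and with fry 21. For the ovulatory response the estimate was 0.0139 and for the extracellular proteases -0.0297, close to or below the preset of 0.01. Their adjusted p still rose, from 6.56e-09 to 0.0312 and from 1.4e-05 to 0.0327. For these lists a higher correlation therefore does not by itself account for the weaker result. Fry does not compare a list with other genes. Under fry, WNT signalling was lower (median -0.0841, adjusted p = 0.0494) where camera ranked it higher without passing. SPRED2 was 0.28 higher after hCG without passing (adjusted p = 0.07) when its probe sets were averaged, against -0.46 in its brightest probe set; those probe sets go both ways. Of the 131 named genes past the threshold, 100 kept direction and call in all the fits made for single genes: the block, repeated quantile normalization, 32 added, an intensity trend with robust variances, averaged probe sets and 1 array left out. The stricter thresholds, the low-signal filter, median centring and array weights were not applied gene by gene. Repeated quantile normalization and median centring moved the median change of all genes by less than 0.1, from -0.09 to -0.09 and -0.05.

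No source used here says that same-numbered arrays share an animal or day. Deviations of same-numbered arrays correlated at 0.00432, 0.152, 0.0264 and -0.0145, and 1 array correlated best with its own number. With a replicate block, 6742 probe sets, 3063 genes (2881 of them shared) and 11 lists passed: the same 9, cholesterol synthesis (adjusted p = 0.0305) and cytokines and chemokines (adjusted p = 0.0406). RMA gives no detection limit, so folds from weak signals are limited by its background correction.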

Other observations

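The scan of gene families and the splits of each list were chosen after the results were seen.

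Several further lists did not pass as a whole. Of 15 immediate early genes, 3 rose, 2 fell and 10 did not pass (the same 3 and 2 adjusted over the list alone, adjusted p of the list = 0.729); FOSL2 rose by 1.30 and ZFP36, which destabilises mRNAs, by 3.04, or 3.64 without array 3 after hCG. The mean of these genes varied between arrays of 1 group, from 9.69 to 10.75 after hCG. Of 23 cytokines and chemokines, 2 rose and 21 did not pass (2 and 0 adjusted over the list alone, adjusted p of the list = 0.0977, or 0.014 without array 3 after hCG). IL1R2, a decoy receptor for interleukin 1, rose by 1.65 (0.74 for the average of its probe sets), and IL1B differed by 2.94 with a wide spread (adjusted p = 0.0827). Of 15 apoptosis regulators, 4 rose, 1 fell and 10 did not pass (4 and 1 adjusted over the list alone, adjusted p of the list = 0.185), with MCL1, which protects from apoptosis, higher by 1.58, and by 0.59 for the average of its 2 probe sets. Of 16 genes of the unfolded protein response, 2 rose, 1 fell and 13 did not pass (2 and 1 adjusted over the list alone, adjusted p of the list = 0.221); DDIT3 fell by 1.39. Of 19 interferon response genes, 2 rose, 1 fell and 16 did not pass (2 and 1 adjusted over the list alone, adjusted p of the list = 0.729), with IFI27 higher by 1.39 and OAS1 lower by 2.88-fold; 2 of the 5 probe sets of OAS1 fell, and the average of all 5 fell by 0.78.

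Of 21 WNT signalling genes, 2 rose, 2 fell and 17 did not pass (2 and 1 adjusted over the list alone, adjusted p of the list = 0.949); TCF7L2 rose by 1.24 and the receptor FZD4 fell by 2.17. Of 20 cAMP signalling genes, 1 rose, 1 fell and 18 did not pass (1 and 0 adjusted over the list alone, adjusted p of the list = 0.769), with RGS2 as the riser; the list's median was -0.20 and its mean 0.02. Camera ranked the WNT and interferon lists higher while their medians and means lay below 0. Of 8 genes of prostaglandin synthesis and receptors, 1 rose, 1 fell and 6 did not pass (1 and 1 adjusted over the list alone, adjusted p of the list = 0.995). Of 15 ribosomal protein genes, 1 rose, 2 fell and 12 did not pass (0 and 1 adjusted over the list alone, adjusted p of the list = 0.729). Among 84 families of genes with a shared symbol stem and at least 15 members, 3 passed (adjusted p = 0.0492 each): RAB genes of vesicle traffic, with 13 of 44 higher and 2 lower; SEC genes, with 9 of 24 higher and 1 lower; and KCTD genes, with 6 of 16 higher and 0 lower. With an estimated correlation 0 of the families passed, at adjusted p = 0.808, 0.962 and 0.962. Of 284 ZNF genes, 57 fell and 13 rose (adjusted p = 0.0573).

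The 8 arrays can be split into 4 and 4 in 35 ways. The real split gave 3359 genes and no other split gave as many (1 of 35 splits, highest other 0). For probe sets it gave 7434, again 1 of 35, with 1 as the highest other. The real split thus stood apart from all others, but 1 of 35 is the lowest share that this test can give. It also takes the replicates as independent, which the sources used here do not say. The number of lists is different: 3 of 35 splits gave at least the 9 of the real one, and the highest other gave 13. The other splits that did so, with 13 and 10 lists, exchange 1 array between the groups and keep part of the real difference. Splits with equal numbers of both groups on each side keep none of it on average and gave at most 6. This test therefore cannot decide whether chance gave that number. For 5 of the 9 lists, the ovulatory response, FSH-stimulated granulosa, cell division, DNA replication and extracellular proteases, no other split reached a p as low, whereas 8 splits did for glycolysis, 11 for oxidative phosphorylation, 5 for the glucocorticoid list and 3 for the cumulus-enriched list, counting the real one. These counts are over all 35 splits, among them those that exchange 1 array, so they do not measure chance alone.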
